A study of Mus musculus with 3 samples.

How the data were processed

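Bone marrow cells from femur and tibia of C57BL/6J mice were enriched on a Ficoll density gradient and profiled with 10x Genomics Single Cell 3' v3.1 chemistry and NovaSeq 6000 sequencing (150 bp paired reads, per the labels), with 1 library each for Sham, MI and MI-E. The authors deposited a matrix of UMI counts per gene and barcode for each library; Cell Ranger 5.0.1 and mouse build mm10 are named in the submitters' processing notes, and the annotation release is not given in the sources used here. The counts were checked to be whole numbers over 32285 genes in each table, with at least 500 (Sham and MI-E) or 501 (MI) UMIs in every barcode, so barcodes under about 500 UMIs were absent from the deposited tables. Groups came from the treatment labels. Gene positions came from GENCODE M21, matched by gene identifier.

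Cells with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept (25053 Sham, 23455 MI and 22506 MI-E). Doublets were scored in each library against 2 simulated doublets per barcode and removed above the threshold between the modes of the simulated scores: 3208 cells of Sham (12.8%), 2476 of MI (10.6%) and 2413 of MI-E (10.7%). The remaining 21845, 20979 and 20093 cells were clustered together on 2000 variable genes, without immunoglobulin and T cell receptor segment, mitochondrial and ribosomal protein genes, with 40 principal components, 20 neighbours and Leiden resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9, seed 1), with no correction between libraries. B lineage-like and neutrophil-like cells were clustered again on their own. Clusters were named from marker lists made before the data were examined; the second naming step, a score over the 8 best markers of a type, was chosen after seeing the clusters. A name needed at least 3 detected markers, and stages without a name were left unnamed. Other work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9.

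UMIs were summed per library and class and given as CPM of the class total, for classes with at least 200 cells in each library. With 1 library per group, no test, p-value, standard error or count of changed genes is given. Shares carry exact Clopper-Pearson intervals, levels exact Poisson intervals, and ratios of levels an exact conditional binomial interval. These are at 95% and for counting error only. Ranges given with log2 ratios of shares combine the opposite interval bounds of the shares compared, so they are wider than 95% intervals. At the depths of these libraries, precision follows the number of cells and UMIs in a class: mature naive B-like cells held 4680146 UMIs in Sham, 2318980 in MI and 3508064 in MI-E. A value at 0 UMIs is given with the limit of 3 counts. Free RNA was estimated from S100a8 and S100a9 in a class as a percent of their level over all cells; in mature naive B-like cells it was 3.96%, 4.69% and 4.01% for Sham, MI and MI-E, and in the remaining named B stages 2.78%, 4.02% and 3.14%.

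Named genes followed a rule fixed before the data were examined: a mean of at least 50 CPM over the 2 libraries compared, leaving out segment, mitochondrial, ribosomal protein and model genes and genes under 0.5 times their all-cell level in both libraries. Genes were ranked by the bound of the interval nearest 1, and the first 5 higher and 5 lower were named in mature naive B-like cells and the first 3 and 3 in the remaining named B stages and in neutrophil-like and monocyte-like cells. The interval of each gene so ranked and named excludes a ratio of 1. The rule also fixed B cell genes, transporter genes and at least 2 members, those with the largest mean CPM, of each gene list described. Some genes that the rule names are not reported here. Lists (37 in all) were fixed before the data were examined, and those described were chosen after their values were seen; some genes stand in more than 1 list. A list value is the median log2 ratio of members with a mean of at least 10 CPM over the 3 libraries, beside its percentile among 10000 random lists of the same size matched in 20 expression bins, as a description only. All 3 comparisons share libraries, so no overlap or correlation between them is given.

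Alternatives, 18 fixed before the data were examined and 3 added after, covered looser and stricter cell filters, doublet treatment, clustering resolution and variable genes, libraries clustered apart, cells thinned to 1000 UMIs, scaling, equal weight of cells, list minimums and matching bins. Median-of-ratios and TMM scaling shift all log2 ratios of MI over Sham by -0.12 and -0.15 in the whole B lineage, -0.15 and -0.17 in the remaining named B stages, -0.10 and -0.11 in immature B-like and -0.27 and -0.26 in erythroid-like cells. For MI-E over Sham the shifts are -0.15 and -0.19 in the whole B lineage, -0.20 and -0.21 in the remaining named B stages, -0.17 and -0.18 in immature B-like, -0.13 and -0.11 in plasmacytoid dendritic-like and -0.12 and -0.09 in T-like cells. The intervals were tested on simulated data from mature naive B-like cells: for folds of 0.5, 0.75, 1.0, 1.5 and 2.0 they held the fold for 96.0%, 90.0%, 95.05%, 90.0% and 92.0% of genes. A simulated scaling factor of 0.8 was recovered as 0.802 and 0.806 by the 2 methods, and 6.4% of 500 lists drawn without a difference lay beyond the 2.5 and 97.5 percentiles. Neutrophil stages were not compared because most Sham cells had no stage name.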

Results

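Bone marrow cells from the femur and tibia of C57BL/6J mice were profiled by droplet single-cell RNA sequencing in 3 groups: Sham, MI (myocardial infarction, made by ligating the LAD, a coronary artery) and MI-E (MI with EMPA, an agent the labels give only by this abbreviation). Each group has 1 library, so no difference below was tested and every value describes these libraries; the number of animals behind each library is not given in the sources used here. The deposited tables hold 99657072 UMIs (counted molecules) in 25721 barcodes for Sham, 127330601 in 23810 for MI and 109451500 in 22857 for MI-E, with medians of 2.65%, 1.80% and 2.43% mitochondrial UMIs. After the cell filter (at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs) and removal of likely doublets, 21845 Sham, 20979 MI and 20093 MI-E cells remained, with medians of 2148, 3155 and 2589 UMIs per cell. Shares carry exact Clopper-Pearson 95% intervals. Levels are UMIs per 1000000 UMIs of a cell class (CPM), and ratios of levels carry exact 95% intervals. All intervals cover counting error only. Cell types are named by marker genes and written as "-like".

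The first comparison, MI over Sham, asks how the marrow differed after infarction. B lineage-like cells, the precursors and naive forms of antibody-producing lymphocytes, made up 18.7% (18.2 to 19.2) of MI cells and 48.5% (47.8 to 49.1) of Sham cells, a 2.59-fold lower share. Neutrophil-like cells, the short-lived phagocytes of early inflammation, made up 31.5% (30.9 to 32.2) in MI and 11.4% (11.0 to 11.8) in Sham, a 2.76-fold higher share. Monocyte-like cells made up 23.1% in MI and 16.5% in Sham, and myeloid progenitor-like cells 6.15% and 2.84% (log2 ratio 1.12, but 0.48 under a stricter cell filter and 1.71 with 4000 variable genes). Erythroid-like cells, the red cell precursors, were lower in MI (4.02% against 6.12%), as were plasmacytoid dendritic-like cells, a source of type I interferon (2.96% against 4.46%). T-like cells stood at 3.34% in MI and 2.32% in Sham, a direction that turned under the stricter filter. Among cells other than neutrophil-like ones, the B lineage-like share was still 2.00-fold lower in MI, at 27.3% against 54.7%. A Ficoll density gradient preceded the assay and can set the share of dense cells such as neutrophils. B lineage-like cells were also shallower in MI than in Sham (median 1063 against 1399 UMIs), and under that filter, with at least 800 genes and 1500 UMIs per cell, the log2 ratio of their share was -3.00 in place of -1.37.

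**Figure D1:**
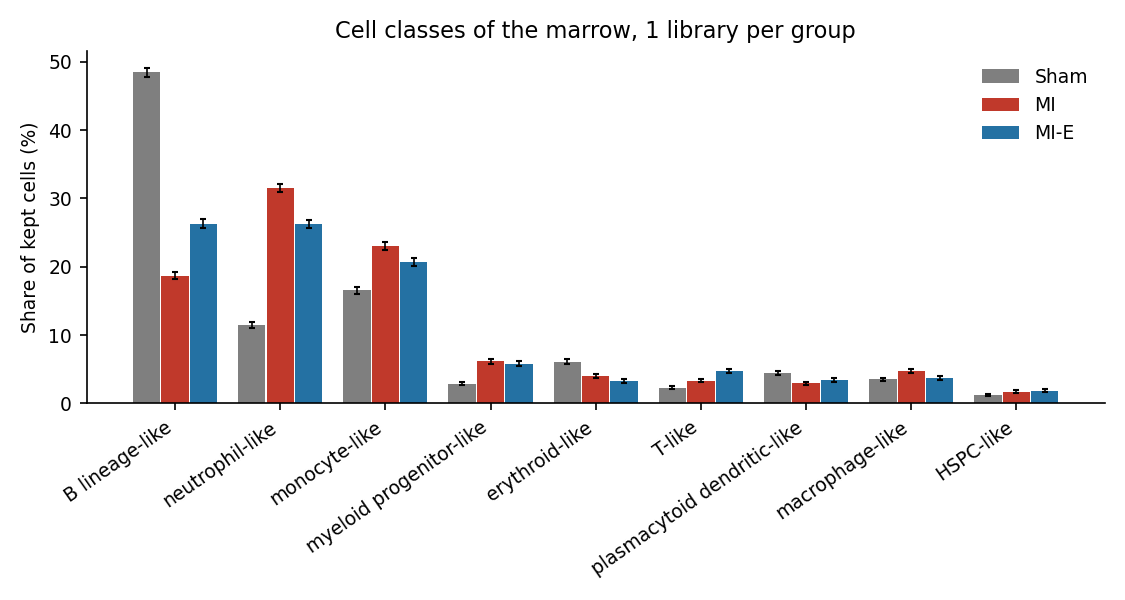
Share of filtered cells (percent) in named classes for the Sham, MI and MI-E libraries, with bars for shares and error bars for exact 95% intervals of counting error. Basophil or mast-like, NK or innate lymphoid-like, plasma cell-like and stromal or endothelial-like cells are not drawn. B lineage-like cells are lowest in MI (18.7%) and neutrophil-like cells highest there (31.5%).

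Within the B lineage, the dividing precursors were the scarcest in MI. Large pre-B-like cells, which divide after assembling a heavy chain, were 1.04% (0.751 to 1.41) of B lineage-like cells in MI and 10.6% (10.1 to 11.2) in Sham, a 10.2-fold lower share resting on 41 MI cells. Pro-B-like cells, the earliest stage, were 2.01% against 6.19%, and small pre-B-like cells, which recombine light chains, 13.8% against 28.1%, a direction that turned at resolution 0.5, where 31.4% of Sham B lineage-like cells had no stage name. The pro-B-like difference was smaller under the stricter filter (8.98% against 12.2%) and with cells thinned (2.83% against 4.92%). Immature B-like cells were 22.98% and 21.7% (log2 ratio 0.08, but -1.46 with each library clustered apart). Mature naive B-like cells, the recirculating end stage, were 55.7% (54.1 to 57.3) of the B lineage in MI and 31.2% (30.3 to 32.1) in Sham. As a share of all cells, though, mature naive B-like cells were 10.4% in MI and 15.1% in Sham. A further 4.46% of MI and 2.18% of Sham B lineage-like cells sat in sub-clusters without a stage name.

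The stage contrast was also present in RNA summed over the whole B lineage, without stage calls. The same cells gave the stage calls, and Top2a and Ighd lead stage sub-clusters, so these sums are not separate support. The list of G2 and M phase genes, which drive mitosis, had a median log2 ratio of -2.22, with 32 of 32 measured members lower in MI, among them Hmgb2, a chromatin protein gene (526 against 2444 CPM), and Top2a, which untangles DNA (66.2 against 450.4 CPM). The list of mature naive B genes had a median of 0.48 with 19 of 22 members higher in MI: Ighd, the IgD heavy chain of naive cells, stood at 917 CPM against 492, and Mef2c, a B cell transcription factor, at 774 against 668, a direction that turned with cells thinned. The first median lay below, and the second above, 100% of 10000 random lists of like expression.

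**Figure D2:**
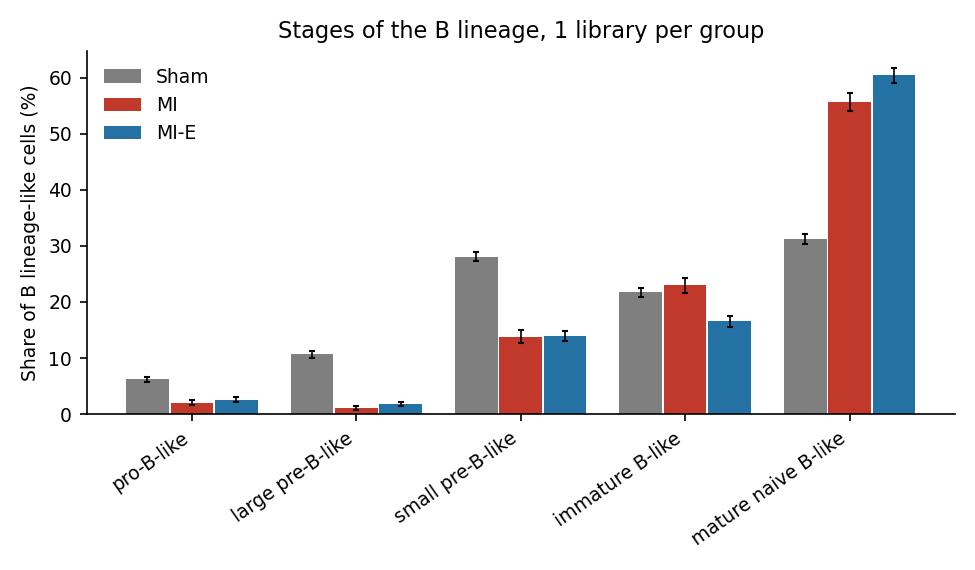
Share of B lineage-like cells (percent) in each B cell stage for the Sham, MI and MI-E libraries, with bars for shares and error bars for exact 95% intervals of counting error. Mature naive B-like cells take 31.2%, 55.7% and 60.4%, and large pre-B-like cells 10.6%, 1.04% and 1.76%.

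In mature naive B-like cells, genes that glucocorticoid hormones induce were higher in MI than in Sham. The glucocorticoid response list had a median log2 ratio of 1.12, above 100% of random lists, with 13 of 16 members higher. Handling of the cells stays open as a cause, since the cold-inducible gene Rbm3 was also higher there (log2 ratio 0.66). Pik3ip1 (ENSMUSG00000034614, chromosome 11, 3330401 to 3342971), an inhibitor of PI3 kinase, was 5.45-fold higher (4.49 to 6.65), at 166 CPM against 30.6. Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), which encodes the glucocorticoid-induced leucine zipper, was 3.04-fold higher (2.77 to 3.33), at 496 against 163 CPM. Zfp36l2, an RNA-binding protein that speeds mRNA decay, was 2.996-fold higher (646 against 216 CPM). Btg1, an antiproliferative gene, was 1868 against 1697 CPM, a difference that turned to lower under both other scalings. Ptpn22, a phosphatase that restrains antigen receptor signals, was 4.63-fold higher, and Ppp1r21 4.57-fold higher. Positions are on mouse build mm10.

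Immediate early and dissociation stress genes were lower in the same cells. The list of them, called the immediate early list here, also holds heat shock genes. It had a median of -0.56, below 100% of random lists, with 23 of 24 members lower. The transcription factor genes Fosb, Fos and Jun were 5.38-fold, 4.31-fold and 4.06-fold lower; Klf2 was 664 against 1032 CPM and Jund 642 against 1008. Jchain and Igha, genes of antibody-secreting cells, were 17.5-fold and 13.1-fold lower, but 1 Sham cell held 415 of the 531 Jchain UMIs and 1740 of the 1935 Igha UMIs there. Without each library's top cell (an alternative chosen after seeing the data), the log2 ratio of Igha in mature naive B-like cells was -0.51 in place of -3.72, and that of Jchain -2.04 in place of -4.13.

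Several genes that mark mature follicular B cells were lower within the mature naive B-like cells of MI. Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694175), the low-affinity IgE receptor CD23, was 2.14-fold lower, at 295 against 631 CPM. Cr2 (ENSMUSG00000026616, chromosome 1, 195136811 to 195176716), the complement receptor CD21, was 1.89-fold lower, at 98.8 against 187 CPM. S1pr1, the receptor that draws lymphocytes into blood, was 179 against 269 CPM, and Ccr7, a lymph node homing receptor, 94.9 against 136. Cxcr4, the receptor that retains cells in marrow, was 2.21-fold higher (1.97 to 2.49), at 263 against 119 CPM. The mature naive B list had a median of -0.31 here, below 99.9% of random lists, with 17 of 22 members lower, Mef2c among them at 945 against 1434 CPM. All 13 measured members of the MHC class II presentation list were lower (median -0.46): H2-Aa stood at 3131 against 3797 CPM, and Cd74, the class II chaperone, had a log2 ratio of -0.60. Of the other genes fixed beforehand, Ighd was 1573 against 1676 CPM, Ighm (the IgM heavy chain) 5157 against 4223, Ms4a1 (CD20) 1025 against 1242, Cd79a 2854 against 3004 and Cxcr5 78.9 against 79.9. The direction of Ms4a1 turned under the stricter cell filter.

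**Figure D3:**
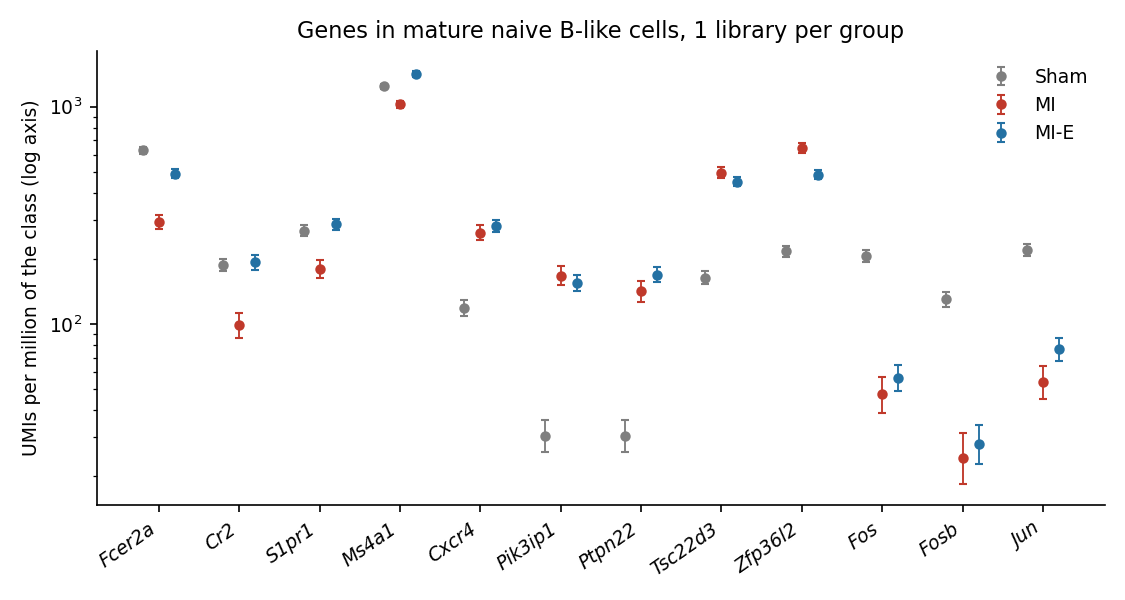
Level (CPM, log axis) of 12 of the genes named in mature naive B-like cells of the Sham, MI and MI-E libraries, with points for levels and error bars for exact 95% Poisson intervals. Fcer2a is 631, 295 and 491 CPM, Cr2 187, 98.8 and 192, and Cxcr4 119, 263 and 283.

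Most Sham mature naive B-like cells (91.3%) fell in a sub-cluster led by Fcer2a and Gpr183, and most MI ones (94.5%) in another led by Icosl, Cd200 and Gpr174. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Free RNA, judged by the neutrophil genes S100a8 and S100a9, stood at 3.96% of the all-cell level in Sham and 4.69% in MI. Other scalings shift all mature naive B-like ratios of MI over Sham by -0.17 (median of ratios) and -0.18 (TMM) on the log2 scale.

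In the remaining named B stages together, the glucocorticoid-induced Tsc22d3 was 6.39-fold higher in MI (511 against 79.9 CPM), Ppp1r21 6.20-fold higher and Sorl1, a sorting receptor, 4.85-fold higher. Genes of dividing cells were lowest: Pclaf, a partner of the replication clamp, was 14.9-fold lower (42.8 against 638 CPM), the linker histone gene Hist1h1b 8.64-fold lower and Stmn1, a microtubule regulator, 8.04-fold lower. These ratios are pooled over stages and carry the difference in stage mix: large pre-B-like cells were 1126 of the 7054 cells in Sham and 41 of 1564 in MI. By stage, the glucocorticoid list was higher in immature B-like cells (median 0.96, 13 of 15 members) and in small pre-B-like cells (median 0.59, 14 of 16 members); Tsc22d3 in the former was 538 against 124 CPM and Cxcr4 in the latter 579 against 362. The type I interferon list, the antiviral genes that interferon induces, was lower in small pre-B-like cells (median -0.80, 14 of 16 members) and in mature naive B-like cells (median -0.19, 16 of 20 members). Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680), an interferon-induced mitochondrial protein, was 283 against 1185 CPM in small pre-B-like and 197 against 684 CPM in mature naive B-like cells. MHC class II genes went the other way from the mature stage, with medians of 0.52 in immature B-like (11 of 13 higher) and 0.45 in small pre-B-like cells (10 of 12 higher); Cd74 was 7353 against 5137 CPM in the former and 588 against 545 CPM in the latter, where it turned with equal weight of cells and without doublet removal. Small pre-B-like cells also split by library: 99.0% of Sham cells sat in a sub-cluster led by Col5a3, Reln and Rag1, and 83.9% of MI cells in another led by Prg3, Nav2 and Rag1.

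Neutrophil-like cells of MI held more RNA of Stfa2 (23.9-fold, 104 against 4.35 CPM) and Cstdc5 (18.4-fold), genes of the stefin family of protease inhibitors, and of Wfdc17 (16.8-fold). Lower in MI were Slc7a11, the cystine importer (5.73-fold), and the early response genes Egr1 (4.57-fold) and Btg2 (2.88-fold). The immediate early list had 20 of 21 members lower (median -0.72; Junb 484 against 795 CPM, Zfp36 382 against 720). The interferon list had 13 of 16 lower (median -0.68; Ifi27l2a 19.3 against 209 CPM, Samd9l 149 against 175), and the NF-kB and inflammatory cytokine list 17 of 22 lower (median -0.48). Within that last list the chemokine gene Ccl6 was lower (171 against 307 CPM) and Nfkbia, the NF-kB inhibitor, higher (201 against 128). Primary granule genes, made early in neutrophil development, were higher for 8 of 9 members (median 0.48), with Serpinb1a at 785 against 532 CPM, while Lyz2, lysozyme, was lower at 2899 against 7315. Of Sham cells, 61.0% fell in a cluster led by Slc7a11, Retnlg and Mmp9, against 0.650% of MI cells, and this cluster mostly of 1 library may be that library, not a type. A cluster with Stfa2 among its leading genes held 38.3% of MI and 3.41% of Sham cells. Another, with Cstdc5 among its leading genes, held 15.5% and 10.7%. The neutrophil-like ratios and list medians are pooled over clusters and may carry this mix. Maturation stages are not compared: 89.4% of Sham against 49.1% of MI neutrophil-like cells had no stage by name. Of these, 1513 Sham and 41 MI cells sat in 1 sub-cluster led by interferon genes (Rsad2, Ifit1, Isg15) and haemoglobin genes (Hba-a1, Hbb-bs). It stayed unnamed because markers of another cell type led. With 4000 variable genes a like sub-cluster (1563 Sham cells) was named mature neutrophil. RNA of erythroid cells may thus add to the interferon levels of Sham neutrophil-like cells, which was not tested.

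In monocyte-like cells the interferon genes were lower in MI to the last member. All 29 measured members of the interferon list were lower in MI (median -1.76, below 100% of random lists). Ifi27l2a was 9.68-fold lower (293 against 2832 CPM), Ifi203 7.27-fold and Irf7, which amplifies interferon output, 6.35-fold lower; Slfn5 was 73.8 against 249 CPM. MHC class II genes were lower for 8 of 8 members (median -1.64; Cd74 98.3 against 652 CPM, the protease gene Ctss 665 against 987), and MHC class I genes for 16 of 16 (median -0.80; B2m 697 against 1557 CPM, H2-D1 869 against 1363). Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute phase protein, was 222-fold higher (147 to 355), at 289 against 1.30 CPM. Il1r2, the decoy receptor for interleukin 1, was 87.1-fold higher (63.1 to 124), and the matrix protein gene Thbs1 7.87-fold higher. S100a8 and S100a9, genes abundant in neutrophil-like cells, together stood at 26042 CPM in monocyte-like cells of MI and 13927 in MI-E against 3205 in Sham. RNA of neutrophils may add to such differences, but monocyte-like cells may also make these transcripts themselves, and the sources were not told apart. In MI neutrophil-like cells Il1r2 was at 224 CPM and Saa3 at 5.15. The immediate early list was lower for 23 of 24 members (median -0.72; Hsp90ab1 659 against 852 CPM), although Hspa8, at 1003 against 1025 CPM, was higher under TMM scaling and with abundant genes left out of the totals. Most Sham cells (78.3%) fell in a cluster led by Slfn5, Ifi204 and Ifi27l2a, and most MI cells (63.2%) in another led by Apoc2 and Vcan.

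**Figure D4:**
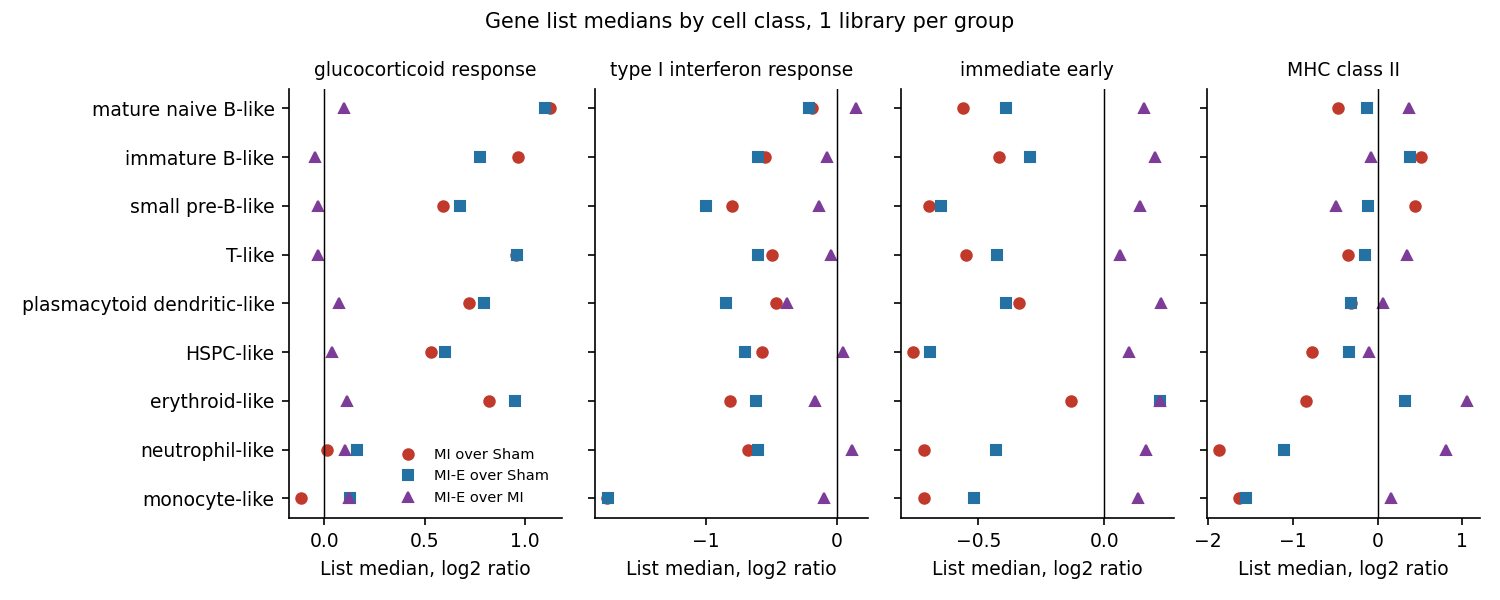
Median log2 ratio of CPM over the measured members of the gene lists, by cell class, for the 3 comparisons. Interferon list medians lie below 0 in every class drawn for MI over Sham, down to -1.76 in monocyte-like cells, and glucocorticoid list medians reach 1.12 in mature naive B-like cells but are 0.015 and -0.11 in neutrophil-like and monocyte-like cells.

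The glucocorticoid list as a whole did not differ one way in myeloid cells: its median was 0.015 in neutrophil-like cells (7 of 13 members higher; Btg1 265 against 596 CPM, Dusp1 236 against 258) and -0.11 in monocyte-like cells (7 of 15 higher; Btg1 499.9 against 541 CPM, Zfp36l2 387 against 554). Its member Fkbp5, though, was higher in both, at 55.8 against 30.1 CPM and 116 against 34.5 CPM. The neutrophil-like median turned to -0.11 without doublet removal and with a 50 CPM minimum and to -0.09 with cells weighted equally. The monocyte-like median turned to 0.14 with cells thinned and to 0.088 with cells weighted equally, Btg1 there turned with equal weights and the stricter filter, and Dusp1 turned under that filter. Among rarer classes, the list was higher in T-like and plasmacytoid dendritic-like cells. Its median in MI over Sham was 0.95 in T-like cells (14 of 17 members; Zfp36l2 964 against 485 CPM, Btg1 975 against 925) and 0.72 in plasmacytoid dendritic-like cells (14 of 17; Zfp36l2 773 against 419 CPM, while Btg1 was 346 against 624). The interferon list was lower in T-like (median -0.49, 26 of 27; Ifi27l2a 224 against 844 CPM), plasmacytoid dendritic-like (median -0.47, 20 of 22; Bst2, which tethers virus particles, 1757 against 2931 CPM) and erythroid-like cells (median -0.82, 18 of 20; Rsad2 94.1 against 486 CPM, Isg15 62.6 against 273). Erythroid-like cells differed by cluster too: one that Rsad2 helps define held 34.4% of Sham and 19.9% of MI ones. S phase genes, which copy DNA, were lower in basophil or mast-like cells (median -1.53, 25 of 26), where E2f8 was 145 against 182 CPM and Rfc2 stood higher at 300 against 251, a direction that turned without doublet removal.

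The second comparison, MI-E over MI, asks how the marrow after infarction differed with EMPA. B lineage-like cells made up 26.3% (25.7 to 26.9) of MI-E cells, a 1.41-fold higher share than the 18.7% of MI. Neutrophil-like cells were 26.2% (25.6 to 26.8), a 1.20-fold lower share, and monocyte-like cells 20.7% against 23.1%. T-like cells were 4.73% against 3.34%, NK or innate lymphoid-like cells 1.54% against 0.953%, and erythroid-like cells 3.29% against 4.02%. Mature naive B-like cells were 15.9% (15.4 to 16.4) of all MI-E cells and 10.4% (10.0 to 10.8) of MI cells, a 1.53-fold higher share. Median depth in the B lineage was 1077 UMIs in MI-E and 1063 in MI.

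Within the B lineage, mature naive B-like cells were 60.4% (59.1 to 61.7) in MI-E and 55.7% in MI. This small difference turned when each library was clustered apart (log2 ratio -0.81 in place of 0.12), where 32.6% of MI-E and 17.5% of MI B lineage-like cells had no stage name, and the share of all cells turned with it (-0.32 in place of 0.61). Immature B-like cells were 16.5% against 22.98%, which also turned with libraries clustered apart. Large pre-B-like cells were 1.76% against 1.04%, counted on 93 and 41 cells, pro-B-like cells 2.59% against 2.01%, and small pre-B-like cells 13.9% against 13.8%; 4.84% and 4.46% had no stage name. Of the large pre-B-like cells, 20 in MI sat in a sub-cluster that held 9 in MI-E and 90 of 1126 in Sham and may not be of this stage; the other 2 sub-clusters held 6 and 15 cells in MI and 46 and 38 in MI-E. Under the stricter filter, large pre-B-like shares were 8.90% in MI-E and 1.44% in MI. In RNA summed over the whole B lineage, the G2 and M phase list was higher for 31 of 32 members (median 0.77). The mature naive B list there was higher for 18 of 22 (median 0.22), with Ighd at 1289 against 917 CPM and Mef2c at 1048 against 774.

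Within mature naive B-like cells, the genes of mature follicular B cells stood higher in MI-E than in MI. The mature naive B list had a median of 0.34, above 100% of random lists, with 19 of 22 members higher, and the MHC class II list a median of 0.37 with 13 of 13 higher. Cr2 was 1.95-fold higher (1.67 to 2.27), at 192 CPM, and Fcer2a 1.66-fold higher (1.52 to 1.82), at 491 CPM. H2-Aa was 4468 against 3131 CPM and Cd74 9275 against 6922. S1pr1 was 287 against 179 CPM, Ighd 2156 against 1573, Mef2c 1434 against 945 and Ms4a1 1414 against 1025. Prkcb, a kinase of B cell receptor signalling, was 1.79-fold higher (356 against 199 CPM), Hvcn1, a proton channel, 1.75-fold, Plekhm3 2.03-fold and Egr3, an early response gene, 2.26-fold, although Egr3 was lower in MI-E under the stricter cell filter. Lower in MI-E were Apoe, a lipid carrier (2.45-fold, 286 against 700 CPM), the protease inhibitor gene Serpina3g (1.97-fold), Pde2a, a cyclic nucleotide phosphodiesterase (1.70-fold, turned under the stricter filter), Slfn2 (1.56-fold) and AW112010 (1.65-fold). Cxcr4 (283 against 263 CPM), Ighm (5073 against 5157), Cd79a (2749.7 against 2854), Cxcr5 (72.7 against 78.9) and Ccr7 (101 against 94.9) differed less.

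The glucocorticoid and interferon lists differed little between MI-E and MI in these cells. The glucocorticoid median was 0.10 (-0.08 under the stricter filter), with 9 of 16 members higher and Zfp36l2 at 487 against 646 CPM, and the interferon median 0.14 (-0.01 with a 1 CPM minimum), with 12 of 20 higher. In T-like cells the glucocorticoid median was -0.03. MHC class II genes again differed in direction between B stages: in small pre-B-like cells 10 of 12 members were lower in MI-E (median -0.49), with Cd74 at 386 against 588 CPM and turned under the stricter filter, and in immature B-like cells the median was -0.07. Over the other named B stages, Hist1h2ap (a histone gene, 7.94-fold), H1f0 (a linker histone gene, 6.12-fold) and Pclaf (4.40-fold) were higher in MI-E, and the eosinophil granule gene Prg3 (2.75-fold), the dynein light chain gene Dynll1 (2.25-fold) and Ifi27l2a (2.18-fold) lower. These pooled ratios also carry the stage mix. Hist1h2ap and H1f0 were also higher in the neutrophil-like and monocyte-like cells described below, so their difference is not particular to B stages. Over all cells they were higher in MI-E than in MI as well. That level includes all these classes and cannot show whether others differed.

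In neutrophil-like cells Hist1h2ap was 2.74-fold, H1f0 2.29-fold and Gadd45a, a stress and growth arrest gene, 1.86-fold higher in MI-E. Thbs1 (2.57-fold), Plin2, a lipid droplet coat protein (2.07-fold), and Dynll1 (1.72-fold) were lower, as were 7 of 9 primary granule genes (median -0.25), although Lyz2 was 3559.7 against 2899 CPM. The cluster with Cstdc5 among its leading genes held 13.3% of MI-E and 15.5% of MI neutrophil-like cells, a mix that these values may carry. The interferon median was 0.11 (-0.02 with equal weight of cells). In monocyte-like cells Il1r2 was 3.41-fold lower in MI-E (56.0 against 191 CPM), Thbs1 3.19-fold and Mgst2, of leukotriene synthesis, 2.49-fold lower. Hist1h2ap (3.83-fold) and H1f0 (2.78-fold) were higher there. All 32 G2 and M phase genes were higher in monocyte-like cells of MI-E (median 0.52), Hmgb2 at 3170 against 2529 CPM and Top2a at 471 against 319. A cluster led by Hist1h1b and Hist1h2ae, with Top2a among its leading genes, held 16.0% of MI-E and 11.3% of MI monocyte-like cells. The G2 and M phase median is pooled over clusters and may carry this mix. The interferon list was lower in monocyte-like cells for 20 of 29 (median -0.10). In basophil or mast-like cells 23 of 26 S phase genes were higher (median 0.60), E2f8 at 212 against 145 CPM. Other scalings shift the neutrophil-like ratios of MI-E over MI by -0.10 on the log2 scale and those of mature naive B-like cells by -0.04 (median of ratios) and -0.03 (TMM).

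The third comparison, MI-E over Sham, asks where the marrow of MI-E differed from that of Sham. B lineage-like cells were 26.3% against 48.5%, a 1.84-fold lower share, and neutrophil-like cells 26.2% against 11.4%, a 2.30-fold higher share. As a share of all cells, mature naive B-like cells were 15.9% in MI-E against 15.1% in Sham (log2 ratio 0.07). That level was not stable: the log2 ratio was -1.23 under the stricter cell filter, -0.59 with cells thinned and -0.86 with libraries clustered apart. The precursors were lower: within the B lineage, large pre-B-like cells were 1.76% against 10.6% (6.05-fold lower), pro-B-like cells 2.59% against 6.19% and small pre-B-like cells 13.9% against 28.1%, the last turned at resolution 0.5. Under the stricter filter, large pre-B-like cells were 8.90% against 23.2%, and pro-B-like cells were nearly level (11.99% against 12.2%; 3.73% against 4.92% with cells thinned). Summed over the B lineage, all 32 G2 and M phase genes were lower in MI-E than in Sham (median -1.50) and all 22 mature naive B genes higher (median 0.75). The mature naive B-like share of the B lineage, 60.4% against 31.2%, had a log2 ratio of 0.95, but of 0.0055 when each library was clustered apart.

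In mature naive B-like cells of MI-E, the glucocorticoid list was higher than in Sham (median 1.10, 14 of 16 members). Most MI-E cells (89.3%) fell in the sub-cluster of most MI cells, and most Sham cells (91.3%) in the other. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a chaperone of the glucocorticoid receptor and a standard readout of the hormone, was 8.43-fold higher than in Sham (6.40 to 11.3), at 108 against 12.8 CPM. Ptpn22 was 5.52-fold, Pik3ip1 5.05-fold, Ppp1r21 4.21-fold and Scd2, a fatty acid desaturase gene, 3.30-fold higher, and Cxcr4 2.39-fold higher. Ifi27l2a was 4.17-fold lower, Fosb 4.65-fold and Fos 3.62-fold lower; the immediate early list was lower for 23 of 24 members (median -0.39) and the interferon list for 13 of 20 (median -0.21). Igha (11.1-fold) and Jchain (9.26-fold) were lower with the same Sham cell behind most of their UMIs. The log2 ratios without each library's top cell were -0.30 for Igha in mature naive B-like cells and -1.08 for Jchain. The mature naive B list was balanced, 12 members higher and 10 lower (median 0.02, but -0.19 under both other scalings), and 9 of 13 MHC class II genes were lower (median -0.13). Cr2 stood at 192 against 187 CPM, Fcer2a at 491 against 631, S1pr1 at 287 against 269 and Ccr7 at 101 against 136. Cr2, S1pr1 and Ms4a1, higher in MI-E by log2 ratios of 0.04, 0.09 and 0.19, turned to lower under both other scalings, which shift all ratios of this class by -0.21.

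Over the other named B stages, Tsc22d3 (4.93-fold), Ppp1r21 (5.01-fold) and Ddit4, an inhibitor of mTORC1 that glucocorticoids induce (4.86-fold), were higher in MI-E than in Sham. Ifi27l2a (5.67-fold), Hist1h1b (5.39-fold) and Hist1h2ae (3.96-fold) were lower. The glucocorticoid list had medians of 0.78 in immature B-like (14 of 15 members) and 0.68 in small pre-B-like cells, and the interferon list was lower in small pre-B-like cells for 15 of 16 members (median -1.001), a median that turned to 0.029 under the stricter cell filter. S phase genes were higher in small pre-B-like cells of MI-E (median 0.54, 16 of 19 members) and lower in immature B-like cells (median -0.57, 18 of 22). Of small pre-B-like cells, 99.0% of Sham and 77.8% of MI-E ones sat in different sub-clusters.

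The interferon list was lower in neutrophil-like and monocyte-like cells of MI-E than in those of Sham. These cells also lay apart by cluster: the cluster of 61.0% of Sham neutrophil-like cells held 2.13% of MI-E ones, and that of 78.3% of Sham monocyte-like cells 2.24%. In neutrophil-like cells Wfdc17 and Cstdc5 were each 11.5-fold and Ifitm1, an interferon-induced membrane protein gene, 8.01-fold higher, while Egr1 (5.55-fold), Thbs1 (4.09-fold) and Slc7a11 (3.32-fold) were lower. Their interferon median was -0.61 (14 of 16 lower) and their immediate early median -0.43 (15 of 21 lower). In monocyte-like cells Saa3 was 197-fold (130.0 to 315), Vcan, a matrix proteoglycan gene of classical monocytes, 5.47-fold and Chil3, a chitinase-like protein gene, 4.66-fold higher. Ifi27l2a (11.0-fold), Irf7 (7.38-fold) and Ifi203 (6.05-fold) were lower there, with all 29 interferon members (median -1.75), 15 of 16 MHC class I members (median -0.73) and MHC class II (median -1.56) lower as well. The immediate early median was -0.52 (20 of 24 lower); Hsp90ab1, at 901 against 852 CPM, turned to lower when cells were weighted equally, thinned or filtered more strictly. List medians were 0.96 (glucocorticoid) and -0.61 (interferon) in T-like cells, 0.80 and -0.85 in plasmacytoid dendritic-like cells, and -0.62 (interferon) in erythroid-like cells. In erythroid-like cells, other scalings shift all ratios of MI-E over Sham by -0.44 (median of ratios) and -0.43 (TMM).

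Sodium-glucose cotransporter genes were almost silent in the marrow. Slc5a2, which encodes the kidney sodium-glucose cotransporter that gliflozin drugs block, had 10 UMIs in all Sham cells, 18 in MI and 9 in MI-E, with ratios of 1.34 (0.589 to 3.26) for MI over Sham and 0.587 (0.232 to 1.38) for MI-E over MI, so no difference was detectable at this depth. Slc5a1, the gut cotransporter gene, had 0 UMIs in every library, which allows up to 0.0384 CPM in Sham, 0.0287 in MI and 0.0337 in MI-E (3 counts per library).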

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

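The search behind these results, for gene lists whose medians lay in opposite directions in 2 B cell stages (at least 0.3 in size and beyond the 1 and 99 percentiles of random lists), was chosen after list values had been seen; no test was planned for it.

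MHC class II presentation genes, which show antigen to helper T cells, stood in opposite directions in different B cell stages. For MI over Sham the median log2 ratio was 0.52 in immature B-like cells (11 of 13 members higher) and 0.45 in small pre-B-like cells (10 of 12 higher), but -0.46 in mature naive B-like cells (13 of 13 lower). For MI-E over MI it was 0.37 in mature naive B-like cells (13 of 13 higher) and -0.49 in small pre-B-like cells (10 of 12 lower). H2-Aa in immature B-like cells was 664 CPM in Sham, 1316 in MI and 1322 in MI-E. The difference between stages was not tested, since each group has 1 library, and no explanation for it was tested.

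S phase genes did the same for MI-E over Sham, with a median of 0.54 in small pre-B-like cells (16 of 19 members higher) and -0.57 in immature B-like cells (18 of 22 lower). Small pre-B-like cells of Sham (99.0%) and MI-E (77.8%) sat in different sub-clusters. This difference was not tested either.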

How the results depend on the processing

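Tests in this part were fixed before the data were examined except 3 chosen after seeing the data: neutrophil-like cells left out of the denominator, the glucocorticoid list without immediate early members, and genes without each library's top cell. No paired analysis was possible because each group has 1 library. Depth limits what can be said of B lineage-like cells, whose median of 1063 UMIs in MI falls under the 1500 UMIs of the stricter filter. Of 1747 gene values under alternatives, 1190 stayed within counting error of the value given, 536 moved and 21 reversed; for list medians these were 402, 191 and 4 of 597, and for shares 396, 131 and 9 of 536. Among those not counted as reversed, 30 gene, 10 list and 28 share values changed sign from a value whose own interval spans 0. List percentiles changed by at most 18.6 points. The interferon list of erythroid-like cells had too few members for a value at a 50 CPM minimum. The cause of the shifts below was not tested, except where stated.

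The share of B lineage-like cells kept its direction in all alternatives, with log2 ratios from -3.00 to -1.002 (MI over Sham), 0.38 to 0.77 (MI-E over MI) and -2.23 to -0.62 (MI-E over Sham). In that order, they were -3.00, 0.77 and -2.23 under the stricter filter, -1.89, 0.59 and -1.30 with cells thinned, and -1.002, 0.38 and -0.62 with neutrophil-like cells left out of the denominator. Neutrophil-like shares were 1.34 and 1.07 for MI and MI-E over Sham without doublet removal, 1.60 and 1.29 with thinning, and -0.20 for MI-E over MI under the stricter filter. Mature naive B-like shares of the B lineage were 0.53 (MI over Sham) and 0.47 (MI-E over MI) under the stricter filter and 0.51, 0.19 and 0.71 (MI-E over Sham) with thinning. The stricter filter left 29.4% of MI and 23.6% of MI-E B lineage-like cells without a stage name, against 4.67% of Sham, and 140 mature naive B-like and 42 small pre-B-like cells in MI, under the minimum of 200, so its values in these classes are less certain. With libraries clustered apart they were -0.81 for MI-E over MI and 0.0055 for MI-E over Sham, and -0.32 as a share of all cells for MI-E over MI; 32.6% of MI-E B lineage-like cells then had no stage name, against 4.84%. Clustered apart, immature B-like cells (MI-E over MI) were at 0.84 and HSPC-like cells (MI over Sham) at -0.12. T-like cells (MI over Sham) were at -0.046 and monocyte-like cells (MI-E over Sham) at -0.015 under the stricter filter, and the latter at -0.074 with 4000 variable genes. At resolution 0.5, small pre-B-like shares were 5.73 and 5.65 for MI and MI-E over Sham, where 31.4% of Sham B lineage-like cells had no stage name, against 2.18% in the main run.

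Among list medians, glucocorticoid response in mature naive B-like cells (MI over Sham) ranged from 0.95 to 1.37, at 0.95 under median-of-ratios, 0.95 under TMM scaling, 0.96 with thinning and 1.37 with a 50 CPM minimum. MHC class II in mature naive B-like cells (MI-E over MI) was 0.33 under median-of-ratios. The interferon list in monocyte-like cells (MI over Sham) was -1.59 without doublet removal, -1.40 under the stricter filter and -2.07 with a 1 CPM minimum, and in small pre-B-like cells (MI-E over Sham) 0.029 under the stricter filter. The glucocorticoid list in monocyte-like cells (MI over Sham) was 0.14 with thinning, 0.088 with equal weight of cells and 0.049 without immediate early members.

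Gene log2 ratios that reversed in mature naive B-like cells under the stricter filter were, for MI-E over MI, Egr3 (-0.38), Pde2a (0.19) and Btg1 (-0.015), and for MI over Sham, Ms4a1 (0.14). Under median-of-ratios and TMM scaling they were Btg1 (-0.032 and -0.037) for MI over Sham, and Ms4a1 (-0.024 and -0.019) for MI-E over Sham; a shift of all genes by the scaling factor is the cause. Under the stricter filter in small pre-B-like cells, Cd74 was 0.093 and H2-Ob -0.51 for MI-E over MI, and H2-Ob 0.17 for MI over Sham. In monocyte-like cells Hspa8 (MI over Sham) was 0.0039 under TMM scaling and 0.00039 with abundant genes left out of the totals, and Hsp90ab1 (MI-E over Sham) -0.14 with equal weight of cells, -0.12 with thinning and -0.16 under the stricter filter. Btg1 in monocyte-like cells (MI over Sham) was 0.020 with equal weight of cells and 0.17 under the stricter filter, and Dusp1 in neutrophil-like cells (MI over Sham) 0.23 under that filter. Rfc2 in basophil or mast-like cells (MI over Sham) was -0.012 without doublet removal, and Mef2c in the whole B lineage (MI over Sham) -0.023 with thinning.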

Other observations

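Of the tests on 3 patterns below, that of free RNA for the interferon genes was written before its result was seen and the other tests after. The genes in this part were chosen after their values were seen.

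Rbm3, a cold-inducible RNA-binding protein gene, was 495 CPM over all cells in Sham, 1162 in MI and 895 in MI-E, and Cirbp, its relative, was 194, 339 and 342 CPM in mature naive B-like cells. Il7r, the receptor for the lymphoid survival factor interleukin 7, was 251, 799 and 745 CPM in T-like cells and 457, 1182 and 1370.3 CPM in small pre-B-like cells. The hormone readout Fkbp5 was 25.2, 91.0 and 103 CPM in T-like cells, 41.9, 221 and 212 in plasmacytoid dendritic-like cells and 34.5, 116 and 139 in monocyte-like cells. Prg2, an eosinophil granule gene, had 2 UMIs in stem and progenitor-like (HSPC-like) cells of Sham, 885 in MI and 1114 in MI-E. Over all cells, Hist1h2ap was 260.4, 199 and 608 CPM and H1f0 36.4, 48.2 and 116 CPM. Stromal or endothelial-like cells were 0.124% of Sham cells, 0.529% of MI and 0.378% of MI-E, from 27, 111 and 76 cells.

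The lower share of B lineage-like cells in MI than in Sham was weighed against technical causes. Dilution by neutrophil-like cells alone is argued against, since the log2 ratio among the other cells was -1.002 (-1.06 to -0.95). Monocyte-like cells (23.1% against 16.5%) and myeloid progenitor-like cells (6.15% against 2.84%) also had higher shares in MI. They stayed in that denominator, so dilution by all myeloid cells together was not tested. Loss of shallow cells before deposit as the only cause is argued against too: it would spare the deep large pre-B-like cells. Yet their log2 ratio lay below that of the shallower mature naive B-like cells by a difference of -4.18 (-4.85 to -3.56), with 41 large pre-B-like cells in MI. Such loss beside another cause is not excluded, as B lineage-like cells were shallower in MI (median 1063 against 1399 UMIs). A difference between animals or preparations unrelated to the operation cannot be told apart from an effect of infarction, because the largest group has 1 library. A loss of B cell precursors after infarction stays open as an untested biological hypothesis.

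The higher glucocorticoid response list in mature naive B-like cells of MI was weighed next. Free RNA from other cells is argued against, since it meets 1.27% of the excess of the 13 members that were higher (21.6 of 1703 CPM). A shift between the named B cell stages is argued against, since the lowest median of the 3 stages was 0.59. A shift within a stage is not covered by these medians. Mature naive B-like cells mostly sat in different sub-clusters, 91.3% of Sham ones in one and 94.5% of MI ones in another. Immature B-like cells, with a median of 0.96, shared their larger sub-cluster (70.9% of Sham and 60.9% of MI ones). Handling of the cells, for example time on ice, stays open: Rbm3 had a log2 ratio of 0.66 (0.55 to 0.77) in these cells with the immediate early list at -0.56, and handling cannot be told apart from the group with 1 library each. Exposure to stress hormones after infarction may also raise these genes and was not tested.

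The lower interferon list in monocyte-like cells of MI was weighed last. Free RNA from other cells is argued against, since the summed level of the 29 members in Sham monocyte-like cells was 2.08-fold that over all Sham cells (5235 against 2520 CPM). The list was lower in the 11 other classes too, with a middle value of -0.55 (from -0.86 to -0.19), so it was not lower in monocyte-like cells only. Those values cannot tell how much of the monocyte-like difference comes from a change of monocyte subtypes. A cluster led by Slfn5, Ifi204 and Ifi27l2a held 78.3% of Sham and 0.682% of MI monocyte-like cells, and no comparison within a single monocyte cluster was run. The -0.86 is of macrophage-like cells, a mixed class whose largest cluster is led by Cd209a and MHC class II genes; clusters like it were named conventional dendritic under the stricter filter and with cells thinned, so this value may be of dendritic cells. The next value is -0.82 in erythroid-like cells. Handling cannot be told apart from the group, with the immediate early list at -0.72 and Rbm3 at 1.51 in these cells and 1 library per group. A higher interferon tone in the Sham animal or animals, or a lower one after infarction, may apply and stays open as untested.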
